A study of Homo sapiens with 2 samples.

How the data were processed

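The deposited files hold UMI counts per barcode and feature, which the submitters made with Cell Ranger (version 7.0.0 per the file headers) before they were deposited. The submitters' processing notes name STAR alignment to GRCh38; the annotation release, the handling of intronic reads and any barcode filter are not given in the sources used here. Each library had 36601 genes and 12 antibody features, and the antibody features held 0 UMIs in both libraries and were not used here. Gene positions came from GENCODE 29 by gene ID, which matched 34616 of the IDs (94.6%), and 3 list genes were found under an older symbol.

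Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 25% mitochondrial UMIs. In replicate 1, 37 barcodes were under the gene limit, 65 under the UMI limit and 78 over the mitochondrial limit; in replicate 2 these were 32, 56 and 57. This left 4454 and 4894 barcodes. Scrublet marked 3 barcodes in replicate 1 and 0 in replicate 2 at its own thresholds; it has not worked as a doublet filter here, so removing the top 4% of scores was added as an alternative. RNA free in the suspension was not removed.

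Counts were scaled to 10000 UMIs per cell, log-transformed, and scaled per gene with values limited to 10. The genes of the 16 fixed lists (321 genes), mitochondrial genes and ribosomal protein genes were left out first, and 2000 variable genes were then chosen over both libraries. These went into 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5, with both libraries together and no batch correction. A marker counted as raised in a cluster when it reached 5 CPM and was 2-fold above the median of the other clusters, with 5 CPM added to both. A cluster took a class name when at least 1/3 of that class's markers were raised and no other class had both 3 or more markers and at least 1/4 of its markers raised. This naming rule was settled after the clusters had been seen and went through 3 versions. The first and the final version gave the same classes; the middle version left the mesenchymal-like cluster unnamed.

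Raw counts were summed per library and class, which gave 14 sums from 2 libraries. The edgeR quasi-likelihood model had 8 coefficients, with the library as a block, and 6 residual degrees of freedom. Those degrees of freedom come from classes within 2 libraries, so they do not describe variation between independent cultures. Of 16537 genes tested, 1471 had served in clustering and were left out of the gene counts. Normalization was TMM, and p-values were adjusted by Benjamini-Hochberg. Each SE of a log2 fold change is the size of that change over the square root of edgeR's F statistic. It was not estimated apart from the test and can be too small for genes near 0 counts in a class. Lists were tested with camera at a preset correlation of 0.01, adjusted over 16 lists, beside an estimated correlation. The lists, the rule that picks the classes of the preset contrast and the test thresholds were fixed before the data were examined; the class names it drew on were not. The contrasts of hepatocyte-like cells with all other classes and of cycling-like with non-cycling classes were added afterwards. Classes were defined on the same counts that were then compared, so p-values between them are smaller than those for classes defined on other data.

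CPM values are scaled by library totals and fold changes by TMM, so small differences in CPM can have the other sign. For genes with 0 counts in a class the lower 95% counting limit of the ratio is given. List medians of phase 1, phase 2 and transporter genes, of which 3, 4 and 2 had 0 counts in a class, stayed at 3.13, 3.32 and 1.79 when those genes were set to their fold against 3 counts over the class.

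In a simulation with 200 changed genes, edgeR recovered 34 of 50 genes changed 1.5-fold, 49 of 50 changed 2-fold, and 50 of 50 changed 4-fold or 8-fold, with 3 false calls. DESeq2 recovered 26, 48, 50 and 50 of 50, with 0 false calls. With edgeR, 2 changed lists and 0 unchanged lists were called. Each changed list held only genes changed in the same direction. Genes were simulated independently and the classes were fixed. Apart from the 200 changed genes, every gene was given the same mean in all classes and libraries. The real contrast called 4264 genes higher and 3807 lower outside the clustering set. The simulation therefore cannot check the preset correlation of camera, or false calls between classes defined on the same counts. Nor can it check scaling or false calls where so many genes differ.

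Co-variation used list genes detected in at least 10% of cells and 1000 random lists matched over 50 expression bins. Chromosome ratios used 6922 autosomal genes outside the clustering set at a CPM of at least 20, in windows of 25 genes. The chromosome medians of the clusters had been seen before the window tests were written.

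Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9 and scikit-learn 1.9.0, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.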

Results

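The series measured how single cells of a human liver model respond to chemicals that trigger stress responses, and the libraries used here hold the cells that received the vehicle alone. HepaRG is an established human hepatic cell line that is sold as a terminally differentiated culture and is used in place of primary hepatocytes in toxicology. The cultures were kept for 7 days, treated with 0.1% DMSO for 24 h, dissociated and captured with a 10x Genomics Chromium droplet kit that reads the 3′ ends of transcripts, with 10000 cells loaded per library. There were 2 libraries, both of the vehicle group, so no treatment comparison was made; the stressed cultures were not analysed here. Replicate 1 held 4591 barcodes and 85475317 UMIs, with a median of 17328 UMIs and 5331 genes per barcode. Replicate 2 held 4998 barcodes and 57246647 UMIs, with a median of 10300 UMIs and 3962 genes. After filtering, 4451 cells of replicate 1 and 4894 cells of replicate 2 remained, and their median mitochondrial shares were 8.91% and 9.16%. Both libraries carry the same biological replicate label, so each SD below measures the spread between these libraries, which may be technical, and no p-value describes variation between independent cultures.

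The most abundant transcripts in both libraries came from mitochondrial respiratory chain genes and iron storage. The 10 genes with the highest mean CPM (counts scaled to the library's UMI total) were MT-CO2, MT-CO3, MT-CO1, MT-ATP6, FTL, FTH1, MALAT1, MT-CYB, MT-ND4 and EEF1A1. The ferritin light chain FTL stood at 13951 ± 453 CPM and the heavy chain FTH1 at 12888 ± 341 CPM (SD, n = 2). Summed over cells, the libraries had a Pearson correlation of 0.999 and a Spearman correlation of 0.988 across 30503 genes on the log2(CPM + 1) scale; these are correlations across genes, which are not independent replicates. Of 10195 genes with a mean CPM of at least 10, 0 differed by 2-fold or more, and the SD of their log2 ratios was 0.06. With 1 library on each side this was a description without a test. Genes higher in replicate 2 included the acute phase genes HP, at 203 CPM in replicate 1 and 256 CPM in replicate 2, ITIH4 and SAA2, with HOPX and APOC3. The share of hepatocyte-like cells, described below, was also higher in replicate 2 (8.17% against 7.01%). Acute phase genes within those cells averaged 876 CPM in replicate 1 and 879 CPM in replicate 2. In every other class or cluster the acute phase list was higher in replicate 2. It averaged 54.4 and 64.1 CPM in cycling-like cells of replicates 1 and 2, and 154 and 182 CPM in cluster 7. Measured levels within the other classes thus differed as well as the share. RNA free in the suspension was not removed, and whether it raised these levels was not tested. Genes higher in replicate 1 were KCNMB2, PRDM10, CXCL13, CCDC127 and GRIA4, the largest log2 ratio among them being 0.28. The libraries shared 10 barcodes, so they were not a single library deposited in duplicate.

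The question of which kinds of cells the vehicle culture contained was approached by clustering. From markers, 3 classes could be named, and the other clusters kept their numbers. Cells that resembled dividing cells made up the largest class at resolution 0.5, with 31.4% of cells in replicate 1 (95% exact Clopper-Pearson interval 30.05 to 32.80%) and 32.9% in replicate 2 (31.5 to 34.2%), a mean of 32.1 ± 1.02% (SD, n = 2). At resolution 0.3 an unnamed cluster was larger, with 32.8% of cells against 27.6% for the dividing cells. At resolution 0.5 this cycling-like class joined 3 clusters in which 7, 5 and 7 of the 11 proliferation markers were raised, among them the topoisomerase TOP2A and the proliferation antigen MKI67. Mesenchymal-like cells made up 14.9% (13.9 to 16.02%) of replicate 1 and 14.5% (13.6 to 15.6%) of replicate 2, with 5 of 12 mesenchymal markers raised: the collagen COL3A1, the growth factor receptor PDGFRB, and the matrix proteins SPARC, LUM and DCN. Hepatocyte-like cells made up 7.01% (6.28 to 7.80%) of replicate 1 and 8.17% (7.42 to 8.98%) of replicate 2, with 15 of 17 hepatocyte markers raised. Albumin (ALB) stood at 16786 CPM in the hepatocyte-like cluster and at 39.2 to 1271 CPM in the other clusters. These intervals cover counting error only, and each share is a share of the captured cells after filters that can change it.

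The names rest on partial marker sets. In the mesenchymal-like cluster the collagen COL1A2 and the fibroblast marker THY1 stood at 0.12 and 0.06 CPM, while the biliary keratin KRT19 was at 1224 CPM, its highest level in any cluster. No cluster met the rule for biliary-like, hepatic progenitor-like, endothelial-like or immune-like cells. The biliary keratin KRT7 reached at most 5.60 CPM and the epithelial adhesion gene EPCAM at most 0.51 CPM in any cluster. The hepatocyte-like class had the highest median mitochondrial share of all clusters, 13.6%, against 8.40% in the mesenchymal-like class, and median depths of 20314 and 13983 UMIs in replicate 1. The remaining 4 clusters kept their numbers. Cluster 0, with 22.8% of replicate 1 and 22.1% of replicate 2, was led by the chemokine CXCL13 and the potassium channel KCNJ16. Cluster 4 (8.43% and 8.40%) carried 4 raised mesenchymal and 7 raised proliferation markers. Cluster 5 (7.98% and 7.48%) was led by the zinc transporter SLC30A8 and the phosphatase PTPRD, and cluster 7 (7.39% and 6.48%) by the transporter SLC47A2, the interleukin-1 decoy receptor IL1R2 and the quinone reductase NQO1.

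**Figure D1:**
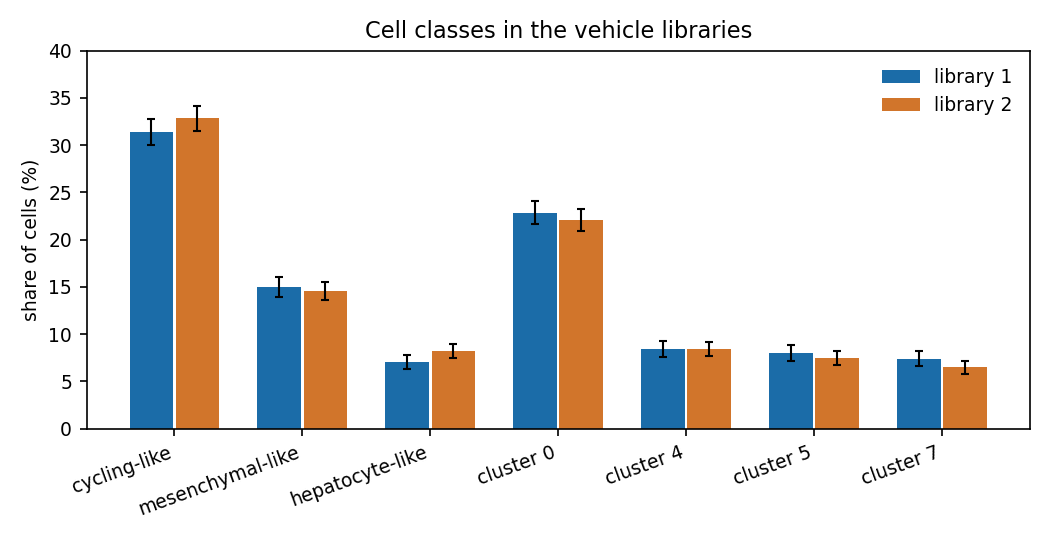
Share of cells (%) in each class or numbered cluster, for library 1 and library 2, with exact 95% binomial intervals as error bars. Cycling-like cells reached 31.4% and 32.9%, and hepatocyte-like cells 7.01% and 8.17%.

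The baseline of the stress responses that the series profiles was read from gene lists. In all cells together, oxidative stress genes had the highest mean level, 1423 ± 30.2 CPM per gene over 25 genes (SD, n = 2), a mean carried by FTL and FTH1; the median gene of the list stood at 303 CPM. Heat-shock genes followed at 291 ± 1.49 CPM over 21 genes, then ER chaperones and other unfolded protein response genes at 181 ± 1.49 CPM over 20 genes and p53 targets of the DNA damage response at 148 ± 1.87 CPM over 26 genes. Hypoxia genes averaged 113 ± 0.26 CPM over 24 genes and integrated stress response genes 59.9 ± 0.85 CPM over 20 genes. By the median gene the order was different, with p53 targets at 134 CPM above heat-shock genes at 93.0 CPM and unfolded protein response genes at 60.1 CPM. All 26 p53 targets, all 21 heat-shock genes and all 20 unfolded protein response genes had a CPM of at least 10. Among the hepatic functions, acute phase and complement genes averaged 154 ± 16.4 CPM over 20 genes in all cells and 877 ± 2.11 CPM in hepatocyte-like cells. Phase 1 drug-metabolising enzymes averaged 53.3 ± 1.22 CPM over 27 genes, 12 of which were below 1 CPM in all cells, against 129 ± 5.19 CPM with 4 genes below 1 CPM in hepatocyte-like cells.

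Hepatocyte-like cells differed from mesenchymal-like cells in liver-specific enzymes and secreted proteins, which were higher, and in actin cytoskeleton genes, which were lower. The conjugating enzymes UGT2B4 and UGT2B15 and the hydroxyproline dehydrogenase PRODH2 had 0 counts in the mesenchymal-like cells of both libraries. By the lower 95% counting limit on the CPM scale, PRODH2 was at least 126-fold higher (28.4 ± 4.27 CPM in hepatocyte-like cells), UGT2B4 at least 102-fold, UGT2B15 at least 76.4-fold and the ankyrin repeat gene ANKS4B, also at 0 counts, at least 64.6-fold (SD, n = 2). The bile acid and steroid sulfotransferase SULT2A1 (182 ± 16.4 CPM) had 2 counts in mesenchymal-like cells, a ratio of 1493 with a 95% counting interval of 413 to 12333. The alcohol dehydrogenase ADH1B also had 2 counts, a ratio of 599 (165 to 4954). SMLR1 and the glyoxylate-detoxifying aminotransferase AGXT had 1 count each, with ratios of 576 (103 to 22804) and 306 (54.4 to 12135). Over 15066 genes outside the clustering set, edgeR's quasi-likelihood test called 4264 higher and 3807 lower at an adjusted p below 0.05, of which 1441 and 1118 changed by at least 2-fold. When cells were first thinned to 4000 UMIs each, fewer genes could be tested, and 2489 of 11706 outside the clustering set were higher and 2206 lower.

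The lowest genes in hepatocyte-like relative to mesenchymal-like cells were led by CYTL1 and PDGFRB. CYTL1, a cytokine-like secreted protein, had 3 counts in hepatocyte-like and 385 in mesenchymal-like cells, a ratio of 100.2 (34.05 to 488) in favour of the mesenchymal-like class. PDGFRB, which also served to name the class, averaged 0.80 ± 1.13 CPM against 37.6 ± 0.88 CPM, a log2 fold change of -5.53 ± 0.30 (SE, adjusted p = 6.6e-17 in edgeR). The adhesion receptor ADGRE1 (log2 fold change -4.51), SPOCD1 (-4.30), the microtubule-associated MAP1B (-3.80), the adhesion molecule PECAM1 (-3.79), itself among the endothelial markers,, PARM1 (-3.71) and the adducin ADD2 (-3.71) followed. The 16 genes named here as highest and lowest were picked among called genes with the same direction in both libraries. Their agreement between libraries was therefore set by the choice and is no added evidence. In GRCh38, with the GENCODE 29 annotation, PRODH2 (ENSG00000250799) spans 35799988 to 35813299 on chromosome 19, SULT2A1 (ENSG00000105398) spans 47870466 to 47886397 on the same chromosome, and CYTL1 (ENSG00000170891) spans 5014586 to 5019472 on chromosome 4.

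Hepatic function lists were higher in hepatocyte-like cells. All 18 tested acute phase and complement genes rose, also when adjusted over the list alone, with a median log2 fold change of 4.44 (camera adjusted p = 4.6e-79). Haptoglobin (HP) stood at 1911 ± 48.8 CPM against 23.2 ± 16.4 CPM, fibrinogen beta (FGB) at 1843 ± 125 against 21.2 ± 9.99 CPM, the orosomucoid ORM1 at 3985 ± 94.5 against 166 ± 30.9 CPM and serum amyloid SAA1 at 4477 ± 138 against 623 ± 49.4 CPM (SD, n = 2). Phase 2 conjugation enzymes had 21 of 22 genes higher and 1 lower (median 3.32, adjusted p = 1.0e-12), with the glutathione transferase GSTA1 at 2760 ± 149 against 147 ± 21.3 CPM. Phase 1 enzymes had 21 of 22 genes higher and 1 lower (median 3.13, adjusted p = 4.5e-22), among them the retinal dehydrogenase ALDH1A1 (log2 fold change 3.99 ± 0.08, SE) and the carboxylesterase CES1 (1.54 ± 0.05). Both splits had the same counts when adjusted over the list alone. Urea cycle, gluconeogenesis and amino acid breakdown genes had 9 of 11 genes higher and 0 lower, with the same counts adjusted over the list alone (median 1.68, adjusted p = 8.5e-12), with HPD, ASL, ASS1 and HGD the most abundant of those called.

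Transporter and bile acid lists were also higher, but their calls depended on how correlation between genes was handled. Drug and bile acid transporters had 13 of 17 genes higher and 2 lower (median 1.79, camera adjusted p = 3.9e-06; adjusted p = 0.0685 with an estimated correlation). The efflux pump ABCB1 averaged 113 ± 11.7 against 5.38 ± 0.65 CPM and the canalicular pump ABCC2 214 ± 19.1 against 70.1 ± 1.28 CPM (SD, n = 2), while the pump ABCC1 was lower (log2 fold change -0.50 ± 0.08, SE, adjusted p = 3.7e-06 in edgeR). Bile acid synthesis genes had 7 of 10 genes higher and 0 lower (median 0.91, adjusted p = 0.0017; adjusted p = 0.0927 with an estimated correlation), including the bile acid conjugating enzyme BAAT at 69.7 ± 2.14 against 0.72 ± 0.29 CPM. Both lists had the same counts when adjusted over the list alone. SAA1, ORM1, GSTA1, UGT2B15, HP and ADH1B have near-identical relatives, so reads matching more than a single copy could be missing from their counts.

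Actin cytoskeleton and adhesion genes were lower in hepatocyte-like cells: 19 of 21 fell and 1 rose, with the same counts adjusted over the list alone (median log2 fold change -1.34, camera adjusted p = 1.4e-30). Beta-actin (ACTB) averaged 1533 ± 193 against 4333 ± 40.4 CPM, gamma-actin (ACTG1) 500 ± 43.4 against 1433 ± 13.1 CPM and annexin A2 (ANXA2) 565 ± 31.6 against 1276 ± 24.3 CPM (SD, n = 2). Metallothioneins split: MT2A (log2 fold change -1.55 ± 0.06, SE) and MT1E (-1.22 ± 0.04) were lower, while MT1F (1.01 ± 0.18) and the zinc exporter SLC30A1 (0.84 ± 0.13) were higher. With 2 of 5 members up and 2 down, adjusted over the list alone as well, the median was 0.01 and the mean -0.18, and camera gave the direction down (adjusted p = 0.0046; adjusted p = 0.0583 with an estimated correlation). The metallothionein call was also lost in other settings given below, and the median log2 CPM ratio changed sign between single libraries. Immediate early genes had 10 of 14 higher and 3 lower, the same counts adjusted over the list alone (median 0.38, camera adjusted p = 0.155). Per the labels, the dissociation buffer of these cells held inhibitors of transcription and translation. With an estimated correlation, the calls that held were those of the acute phase, phase 1, phase 2, nitrogen and glucose, and cytoskeleton lists.

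Stress-response genes moved in both directions between these classes. Oxidative stress genes had 14 of 24 higher and 5 lower, 15 and 5 when adjusted over the list alone (median log2 fold change 0.18, camera adjusted p = 2.4e-04; adjusted p = 0.0685 with an estimated correlation). FTL rose (0.41 ± 0.03, SE) while the redox genes TXN (-0.60 ± 0.04) and TKT (-0.40 ± 0.04) fell. p53 targets had 2 of 26 higher and 16 lower, 2 and 17 adjusted over the list alone (median -0.32, adjusted p = 0.0059; adjusted p = 0.154 with an estimated correlation). Among them GADD45A averaged 109 ± 9.98 against 212 ± 9.41 CPM, BAX 153 ± 3.54 against 244 ± 16.7 CPM, the p53 inhibitor MDM2 606 ± 10.9 against 836 ± 19.6 CPM and the cell cycle inhibitor CDKN1A 257 ± 17.8 against 339 ± 10.2 CPM (SD, n = 2). Sensors and regulators had 8 of 19 higher and 3 lower, the same counts adjusted over the list alone (median 0.19, adjusted p = 0.0219; adjusted p = 0.0685 with an estimated correlation). The camera call of the sensor list was also lost in other settings given below, among them thinned cells and DESeq2. The lipid sensor PPARA was higher (1.75 ± 0.08), and HIF1A (-0.60 ± 0.05) and the amino acid sensor EIF2AK4 (-0.45 ± 0.06) were lower.

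The other stress lists did not pass camera in this comparison. Unfolded protein response genes had 10 of 20 higher and 7 lower, 11 and 7 adjusted over the list alone (median 0.16, adjusted p = 0.457). The abundant ER chaperones HSP90B1 (log2 fold change -0.52 ± 0.04, SE), CALR (-0.40 ± 0.04), PDIA6 (-0.57 ± 0.04) and HSPA5 (-0.23 ± 0.04) were all lower. Integrated stress response genes had 5 of 18 higher and 4 lower, 5 and 3 adjusted over the list alone (median 0.08, mean 0.22, direction down, adjusted p = 0.990), with the serine synthesis gene PSAT1 at -0.71 ± 0.08. Heat-shock genes had 6 of 21 higher and 9 lower, the same counts adjusted over the list alone (median -0.08, adjusted p = 0.148); the mitochondrial chaperone HSPD1 rose by 0.69 ± 0.04 on the log2 scale and the cytosolic HSP90AB1 fell by 0.42 ± 0.03. Hypoxia genes had 14 of 24 higher and 4 lower, the same counts adjusted over the list alone (median 0.41, adjusted p = 0.159), with ENO1 (0.56 ± 0.04), PGK1 (0.42 ± 0.05) and BNIP3 (0.63 ± 0.06) higher.

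**Figure D2:**
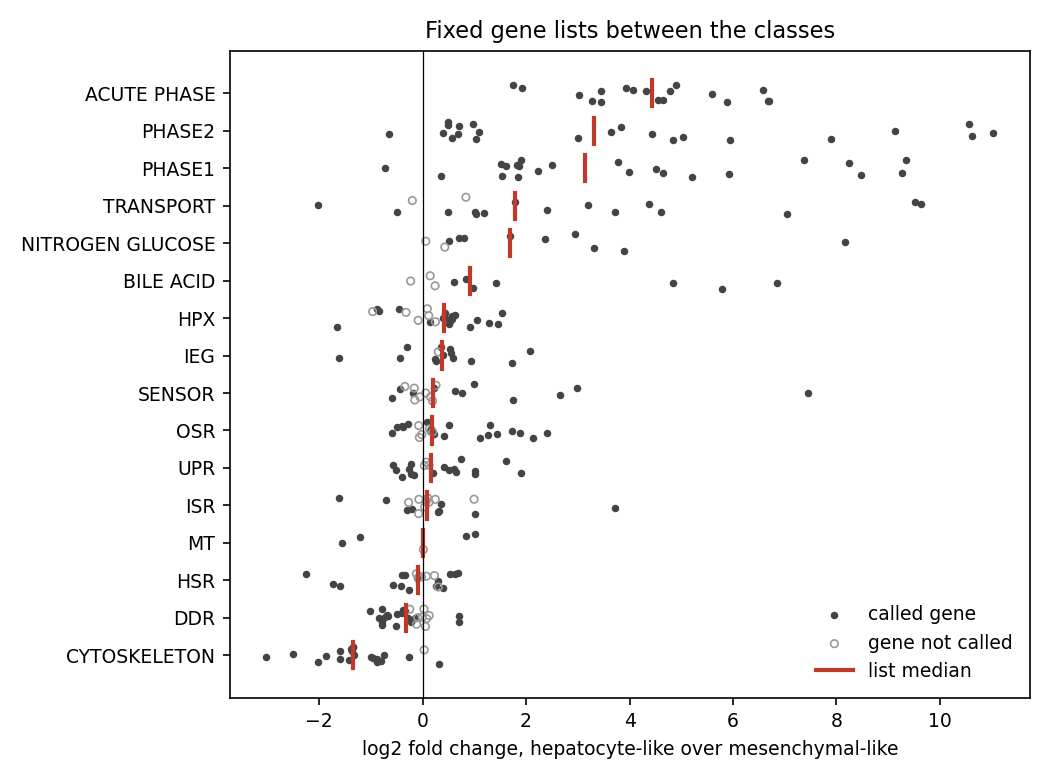
Log2 fold change of each tested gene (points) between hepatocyte-like and mesenchymal-like cells, by gene list, with the list median as a red bar: UPR, unfolded protein response; ISR, integrated stress response; OSR, oxidative stress; HSR, heat shock; HPX, hypoxia; DDR, p53 targets; MT, metallothioneins; IEG, immediate early genes. Medians run from -1.34 for the cytoskeleton list to 4.44 for the acute phase list; scaling by library totals alone moves all values by about -0.17 and turns the medians of UPR, ISR, OSR and MT negative.

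Scaling affected small changes in this comparison. With library totals alone in place of TMM (trimmed mean of M values) factors, the median of all genes was -0.17, and 3051 genes were called higher and 5577 lower. Under that scaling the medians of the unfolded protein response (-0.02), integrated stress response (-0.10), oxidative stress (-0.00068) and metallothionein (-0.16) lists turned negative, and PRDX1 (0.09 with TMM) and LDHA (0.15 with TMM) changed sign. The hepatocyte-like class had the higher mitochondrial share beside each of these lists.

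Genes of the same stress response varied together from cell to cell in the vehicle culture. Within the cycling-like class, the largest at resolution 0.5, the mean pairwise correlation of oxidative stress genes was 0.174 in replicate 1 and 0.148 in replicate 2, and that of integrated stress response genes was 0.139 and 0.100. Those lists, p53 targets (0.083 and 0.054) and unfolded protein response genes (0.067 and 0.053) lay above all 1000 random gene lists of the same size and expression in both libraries. Heat-shock genes (0.081 and 0.043) reached percentiles of 100 and 99.9. Hypoxia genes (0.016 and 0.0093) reached percentiles of 96.9 and 85.1, with 70.7 and 97.3 in the largest single cluster of the class and 93.7 and 93 after thinning, so their co-variation was not set apart from random lists. With cells thinned to 4000 UMIs the means fell to 0.093 and 0.096 for oxidative stress, 0.036 and 0.046 for integrated stress response, 0.025 and 0.027 for unfolded protein response and 0.019 and 0.021 for p53 target genes, still above all random lists. Heat-shock genes fell to 0.013 and 0.018 after thinning, at percentiles of 98 and 99.9. Cells are not replicates, and these percentiles describe each library.

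Clusters 7 and 5 differed from the others along whole stretches of a chromosome; this was measured after the clusters had been seen. In cluster 7, the median log2 ratio of chromosome 2 genes to the other clusters, over genes outside the clustering set, was 0.47 in replicate 1 and 0.48 in replicate 2. All 20 windows of 25 genes along chromosome 2 lay above 0.2 in both libraries, against 1 of 243 windows on the other autosomes in that cluster. Of its cells, 93.6% in replicate 1 and 92.1% in replicate 2 had a chromosome 2 share of UMIs above the 95th percentile of cluster 0, against 32.0% and 33.6% in cycling cluster 8, the next highest. In cluster 5, 3 windows of chromosome 8 from 614746 to 39105144 (GRCh38) were lower than in the other clusters, with medians from -0.49 to -0.26. A run of 6 windows from 55773142 to 144314722 was higher, with medians from 0.22 to 0.39. The window between them, from 41490396 to 55773407, was near 0 (-0.08 in replicate 1 and 0.04 in replicate 2). Among the other 196 pairs of cluster and chromosome, the largest shift of the chromosome median was 0.11 (cluster 4, chromosome 13). Such a median can hide stretches that move in opposite directions, and windows were not examined in the other clusters.

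**Figure D3:**
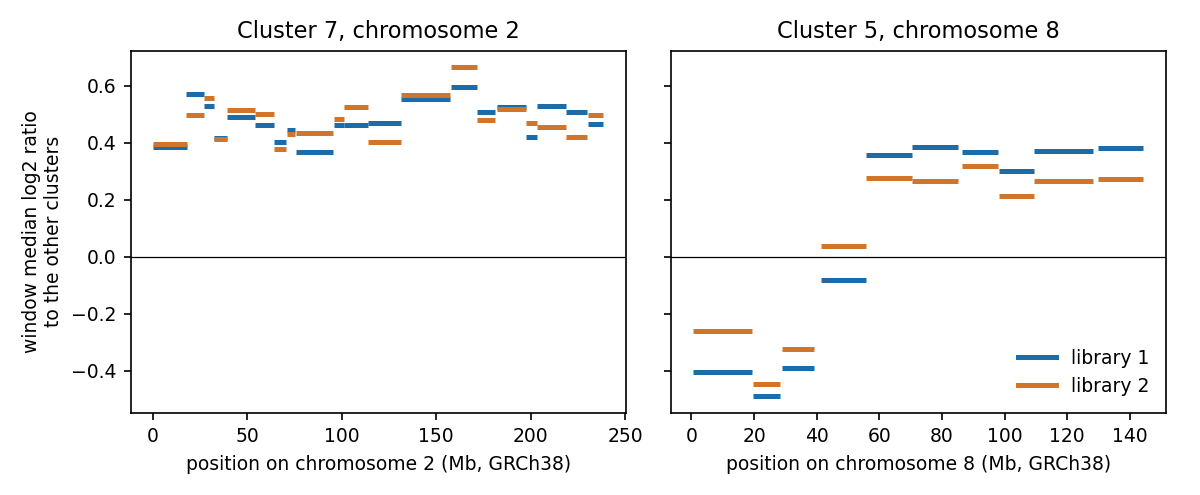
Median log2 ratio to the other clusters of windows of 25 genes (horizontal lines) against position in Mb, for chromosome 2 in cluster 7 and chromosome 8 in cluster 5, in each library. Every chromosome 2 window lies between 0.37 and 0.67. Chromosome 8 windows change from at most -0.26 to at least 0.22 along the chromosome, with a window between them at -0.08 and 0.04.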

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

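Removal of the top 4% of doublet scores and clustering without chromosome 2 or chromosome 8 genes were chosen after the data were seen; the other settings of this part were planned. With cells thinned to 4000 UMIs, hepatocyte-like against mesenchymal-like cells gave 2489 genes higher, 2206 lower and 728 lower by at least 2-fold. These counts are over 11706 genes outside the clustering set, against 15066 without thinning.

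With an estimated correlation, camera no longer called oxidative stress, sensor and transporter genes (adjusted p = 0.0685 each), p53 targets (0.154), bile acid genes (0.0927) or metallothioneins (0.0583). The fry test asks whether the genes of a list changed at all, while camera sets them against the other genes. Its calls therefore answer another question and add nothing to those of camera. With fry, unfolded protein response (4.9e-05), heat-shock (0.0020), hypoxia (4.9e-05) and immediate early genes (2.5e-05) were called. At resolution 0.3 heat-shock (0.0390) and hypoxia genes (0.0189) were called. Library totals alone called heat-shock genes (0.0161). Without a low-count filter hypoxia (0.0074) and immediate early genes (0.0078) were called, and sensors (0.110) and metallothioneins (0.609) were not. Sensors and metallothioneins were not called at a mitochondrial limit of 15% (0.0660 and 0.109), at resolution 1.0 (0.0533 and 0.100) or with only the 2 classes compared (0.0893 and 0.333), where immediate early genes were called (0.0472). Sensors were not called after thinning (0.0560) or with DESeq2 (0.137).

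Without the replicate block, 4210 genes were higher and 3743 lower; metallothioneins lost their call (adjusted p = 0.0715) and no other list call changed. Leave-one-out values of the metallothionein median log2 CPM ratio ran from -0.27 to 0.29, with a change of sign.

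Class shares for cycling-like, mesenchymal-like and hepatocyte-like cells were 27.0%, 16.2% and 5.48% at a mitochondrial limit of 15%, 28.2%, 15.5% and 5.91% with no cell filter, 27.6%, 18.2% and 5.17% at resolution 0.3, and 27.3%, 15.2% and 8.46% after removal of the top doublet scores. The first 2 classes were 30.9% and 14.0% at resolution 1.0, and mesenchymal-like cells were 14.3% with doublets kept. With list genes kept in clustering mesenchymal-like and hepatocyte-like cells were 16.3% and 5.94%, without chromosome 8 genes hepatocyte-like cells were 9.52%, and without chromosome 2 genes cycling-like cells were 27.6%. At resolution 0.3 an unnamed cluster, with 32.8%, was larger than the cycling-like class.

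Co-variation within the main class, HSR (heat shock), fell to percentile 98.95 after thinning, and that of HPX (hypoxia) to 79.8 among genes detected in at least 25% of cells. Over 80 named genes and 14 settings (1120 values), 1086 kept their call and 31 lost it. Another 3 changed sign: PRDX1 (-0.0907) and LDHA (-0.0262) with library totals alone, and KLF6 (-0.0045) without the top doublet scores.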

Other observations

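The contrasts of this part, the co-variation in hepatocyte-like cells, mesenchymal-like cells and cluster 0, and the chromosome and cluster 4 tests were chosen after the clusters had been seen. Cycling-like cells had more integrated stress response and heat-shock transcripts than each non-cycling class. Cluster 4, with its proliferation markers, was left out of the non-cycling side. Cluster 5 stayed on it, though its TOP2A (218 CPM) and MKI67 (119 CPM) lay above those of cluster 0 (62.5 and 42.9 CPM). Cycling-like cells had fewer acute phase transcripts than the average of the non-cycling classes, though not clearly fewer than mesenchymal-like cells (59.2 ± 6.87 against 64.9 ± 7.68 CPM per gene). Integrated stress response genes had 15 of 18 higher and 1 lower (median log2 fold change 0.56, camera adjusted p = 5.7e-05; adjusted p = 0.134 with an estimated correlation), with the serine synthesis gene PSAT1 at 151 ± 1.75 against 72.4 ± 2.58 CPM (SD, n = 2). Heat-shock genes had 16 of 21 higher and 1 lower (median 0.29, adjusted p = 1.7e-05; adjusted p = 0.134 with an estimated correlation), led by the chaperones HSP90AA1 (log2 fold change 0.63 ± 0.03, SE) and HSPA8 (0.46 ± 0.03). Acute phase genes had 0 of 18 higher and 16 lower (median -1.34, adjusted p = 9.7e-18; adjusted p = 0.128 with an estimated correlation), including SAA2 (-2.02 ± 0.05) and fibrinogen gamma, FGG (-1.99 ± 0.07). Hypoxia genes fell in 17 of 24 (adjusted p = 0.0053; 0.207 with an estimated correlation), and unfolded protein response genes in 15 of 20 (adjusted p = 0.0088; 0.134 with an estimated correlation), including HSPA5 (-0.45 ± 0.03). No list call of this contrast held with an estimated correlation, and edgeR called 4433 genes higher and 4246 lower.

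Against all other classes together, hepatocyte-like cells again had higher liver enzymes. CYP2C8, a drug-metabolising cytochrome P450, averaged 29.03 ± 0.38 against 0.15 ± 0.02 CPM, and FGF21 co-receptor KLB 11.0 ± 2.08 against 0.13 ± 0.03 CPM (SD, n = 2). The galectin LGALS1 (log2 fold change -2.41 ± 0.07, SE) and the tropomyosin TPM4 (-2.48 ± 0.06) were lower. All 18 acute phase genes rose, and 18 of 26 p53 targets fell and 3 rose (adjusted p = 5.8e-04; 0.110 with an estimated correlation). With an estimated correlation the calls that held were the same 5 lists as in the preset contrast. All 6 stress lists co-varied above all random lists in hepatocyte-like and mesenchymal-like cells in both libraries; for hypoxia genes the mean correlations were 0.165 and 0.1496 in hepatocyte-like cells (random medians 0.0084 and 0.0084) and 0.097 and 0.047 in mesenchymal-like cells (0.0045 and 0.0049). In cluster 0 hypoxia genes reached percentiles of 99.8 and 88.3 only.

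Cluster 7 had higher levels along all of chromosome 2; the design, with 1 group, gives no biological difference to set against the other explanations. An extra copy of chromosome 2 in these cells fits: 100% of windows were raised, and the medians of 0.47 and 0.48 lay below the 0.585 of 3 copies against 2. Clustering on chromosome 2 genes is argued against, since a cluster with a median of 0.46 formed without any of them. Depth is argued against, since the median was 0.47 with thinned cells. Copy number was inferred from RNA alone, so an extra copy remains a candidate explanation.

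Cluster 5 had chromosome 8 genes higher on most of the chromosome and lower at its start. A whole extra copy is argued against by the 3 lowered windows: the 60% of windows raised lay between the bounds written for that test, and the lowered windows were made to count only after they had been seen. Clustering on chromosome 8 genes (0.21 without them) and depth (0.17 with thinned cells) are argued against as well. Within the cluster, cells with a high share from the raised windows had lower levels of the lowered windows. The log2 difference was -0.59 in the library where it was smaller in size, against -0.02 to 0.07 in other clusters. Loss of the lowered windows and gain of the raised ones in the same cells is therefore a candidate explanation. The window between them had a median near 0 (-0.08 and 0.04). That median cannot tell an unchanged stretch from lowered and raised genes mixed within the window. In chromosome 8 share, 50.1% of cluster 5 cells in replicate 1 and 36.3% in replicate 2 exceeded the 95th percentile of cluster 0. That share takes in lowered and raised windows together, so it cannot tell how many cells carry the change. Cluster 5 cells with a low share from the raised windows had lowered-window levels of 5192 and 5120 in replicates 1 and 2. Those with a high share had 2999 and 3405. Low-share cells of the other clusters had 5043 to 5548 on the same scale, so cluster 5 may be mixed.

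Cluster 4 carried mesenchymal markers (COL3A1, PDGFRB, SPARC, DCN) and proliferation markers together, and the first tests of doublets left them open: the fractions of partner levels summed to 1.19 at the lowest (bounds 1.1 and 1.3), and 33 genes lay above every partner (bounds 10 and 50), THBS1 and CD44 among them. Acute phase genes stood at 23.9 ± 4.43 CPM per gene, against 64.9 ± 7.68 in mesenchymal-like and 59.2 ± 6.87 in cycling-like cells (SD, n = 2), and their median over the lowest level a mixture allows was at most 0.84, which alone missed its bound of 0.8. Taken partner by partner, which was done after those values were seen, doublets are argued against as the whole cause: the sums were 1.90 and 2.05 with cluster 1 and 1.66 and 1.76 with cluster 3, and with cluster 8 the acute phase ratios were 0.43 and 0.47. Blends of these partners restate this, with 0 of 66 within both bounds in either library. The median UMIs per cell of cluster 4 were 0.53 to 0.75 of the summed medians of its partners. Its median doublet score, 0.041, was the lowest of all clusters, though Scrublet had not worked as a filter here. Dividing mesenchymal-like cells were not tested as an explanation, and single doublets within the cluster are not ruled out.

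UBE2C, a proliferation marker, stood at 0.11 to 0.37 CPM in every cluster, and the apolipoprotein APOA2 at most at 0.32 CPM, while TOP2A reached 1760 CPM and APOA1 209 CPM; whether the low values reflect expression or the annotation was not tested, so they are not read as absence.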
